A study of Mus musculus with 8 samples.

How the data were processed

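CUT&Tag libraries for CHD4, H3K4me3, p300 and an IgG control were made from proliferating iMOPs and from iMOP-derived neurons, 1 library for each antibody and state and 8 in all. Per the labels' protocols, 500000 cells entered each library, tagmentation used a protein A-Tn5 kit, and paired reads of 150 bp were sequenced. The submitters' processing notes name Bowtie2, deepTools, SEACR and the build mm10, with no versions, parameters or roles; how the IgG libraries, duplicate reads and thresholds were treated is not given in the sources used here. The labels do not say whether a list pools several libraries, and each was treated as 1 library. The IgG libraries were not analysed here.

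The 6 peak lists have the 6 columns of SEACR output: chromosome, start, end, total signal, highest signal and the position of the highest signal. The signal values are those the authors deposited. Their scaling is not given in the sources used here, so signal was used only to rank or trim peaks within a list. Coordinates run in steps of 50 bp apart from 6 values, so positions are known to that step, and they are printed counted from 1. Total signal grows with the width of a peak, so ranking by it favours wide peaks. No read counts were used, so depth is unknown and a shorter list can come from a shallower library, a stricter threshold or fewer sites.

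Everything below was computed from the lists with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Peaks counted as overlapping when they shared at least 1 bp. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only, since peaks and genes are not replicates; for this reason no p-values are given. Expected overlaps came from 100 shuffles of peaks within their chromosome, over the span that holds genes or peaks.

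Genes came from a RefSeq table of the mouse assembly GRCm38.p6, whose coordinates are those of mm10, with 21887 protein-coding genes on numbered chromosomes, X and Y. The table gives the span of each gene without strand or transcripts. The planned window around transcript starts was therefore replaced by 1 kb either side of both annotated ends of a gene. As a check, 13960 genes longer than 10 kb were used, of which 5855 had H3K4me3 at exactly 1 end. CHD4 lay at the marked end of 22.8% of these in proliferating cells and 16.4% in neurons, and at the unmarked end of 1.78% and 2.92%. A planned search for sequence elements was not run, since no genome sequence was used here.

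Before the data were examined, 20 gene lists (449 distinct genes, all found in the table) were fixed, including markers of hair cells, glia, mesenchyme, blood and liver. For each list and state the number of members with CHD4 at a gene end was set against 10000 random lists of the same size, drawn from all protein-coding genes and again from genes with H3K4me3 at an end in that state. Percentiles describe these libraries and are not tests between states. Named genes followed a rule also fixed beforehand: 7 genes always named, members of each list that differed between the states or had the strongest shared peaks, the 8 strongest CHD4 peaks at gene ends in each class, the 5 widest H3K4me3 peaks per state, and the 5 strongest CHD4 peaks away from gene ends at axon guidance genes in each state. A part of these is left out for length. Further members named for a list, genes named for their H3K4me3 calls, and the regions in the closing section were chosen after their values were seen.

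The script was tested on simulated data for the proliferating CHD4 list over 21887 genes: all 2444 planted overlaps were recovered, 95.5% of simulated lists with a 4-fold excess stood above all but 2.5% of random lists, and 3.5% of lists without an excess did so. The alternatives tried were: at least 50% of a peak covered, a gap of up to 1 kb counted as overlap, the stronger 50% of each list by total signal, lists of equal size for each antibody, and gene windows of 500 bp and 2.5 kb. Chosen after seeing the data were a restriction to numbered chromosomes, X and Y, and the use only of gene ends with H3K4me3. The test of histone genes in the closing section was first run against random gene sets, and replaced by shifts along the gene order because those genes are clustered. Only the result of the shifts is given here.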

Results

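CHD4 is the ATPase of the NuRD chromatin remodelling and deacetylase complex. Its binding was profiled by CUT&Tag, in which an antibody directs a transposase to cut and tag the surrounding DNA. The cells were mouse immortalized multipotent otic progenitors (iMOPs), a line with properties of inner ear progenitors, either proliferating in 20 ng/ml bFGF or differentiated into neurons in medium with 1 µM K03861. Alongside CHD4, H3K4me3 (a histone mark of active promoters) and p300 (an acetyltransferase found at enhancers and promoters) were profiled, each in 1 library of 500000 cells per state. The 6 deposited peak lists were compared; the 2 IgG control libraries were not analysed here, so no background level stands beside the values. Read depth per library is unknown, and with 1 library per group no difference between the states has a replicate check. Exact (Clopper-Pearson) 95% intervals are given for shares of peaks or genes and cover counting error only.

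The covered length of the lists changed in different directions between the 2 states, while the number of peaks was lower in neurons for every antibody. CHD4 had 4919 peaks over 19.4 Mb in proliferating cells and 4599 peaks over 29.2 Mb in neurons, where the median peak was wider (5200 bp against 3400 bp). H3K4me3 had 7472 peaks over 31.3 Mb in proliferating cells and 5625 over 26.6 Mb in neurons. The p300 list was the shortest in both states, with 3144 peaks over 12.5 Mb and 965 peaks over 4.49 Mb. How far the length of a list depends on sequencing depth or on the calling threshold cannot be read from the lists.

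The first comparison asks which CHD4 sites differ between progenitors and neurons. Many sites were listed in both states, among them those at Epha4, an axon guidance receptor, at Sox2, a regulator of otic progenitors, at Tubb3, a neuronal tubulin, at the cell cycle inhibitor gene Cdkn1b and at Chd4 itself. Of the proliferating CHD4 peaks, 3258 of 4919 (66.2%, interval 64.9 to 67.6) overlapped a neuron CHD4 peak by at least 1 bp, and 3100 of 4599 neuron peaks (67.4%, 66.0 to 68.8) overlapped a proliferating one. Shuffling peaks within chromosomes 100 times gave mean overlaps of 2.08% and 2.14%. This left 1661 CHD4 peaks listed in proliferating cells only and 1499 in neurons only. Peaks listed in 1 state only were weaker: their median rank was the 25.7th percentile of total signal in the proliferating list and the 34.8th in the neuron list, against the 62.9th and 58.6th for peaks listed in both.

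CHD4 overlapped the active promoter mark less often in neurons. In proliferating cells 42.2% of CHD4 peaks (40.8 to 43.6) overlapped an H3K4me3 peak of the same state, and in neurons 26.8% (25.5 to 28.1). CHD4 peaks that overlapped a p300 peak made up 58.1% (56.7 to 59.4) in proliferating cells and 20.0% (18.8 to 21.1) in neurons, and those that overlapped neither mark made up 26.3% (25.1 to 27.6) and 56.4% (55.0 to 57.9). The neuron p300 list was also the shorter one. With the lists of all 3 antibodies trimmed to equal size by total signal, the p300 shares were 20.8% and 20.0%, the shares with neither mark 49.0% and 56.4%, and the H3K4me3 shares 38.2% and 26.8%. Of these differences the one for H3K4me3 kept a comparable size in that setting, at 11.4 percentage points. Set against the same H3K4me3 list, the untrimmed CHD4 lists lay closer together. The neuron H3K4me3 list was overlapped by 33.9% of proliferating and 26.8% of neuron CHD4 peaks, and the proliferating H3K4me3 list by 42.2% and 31.9%.

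**Figure D1:**
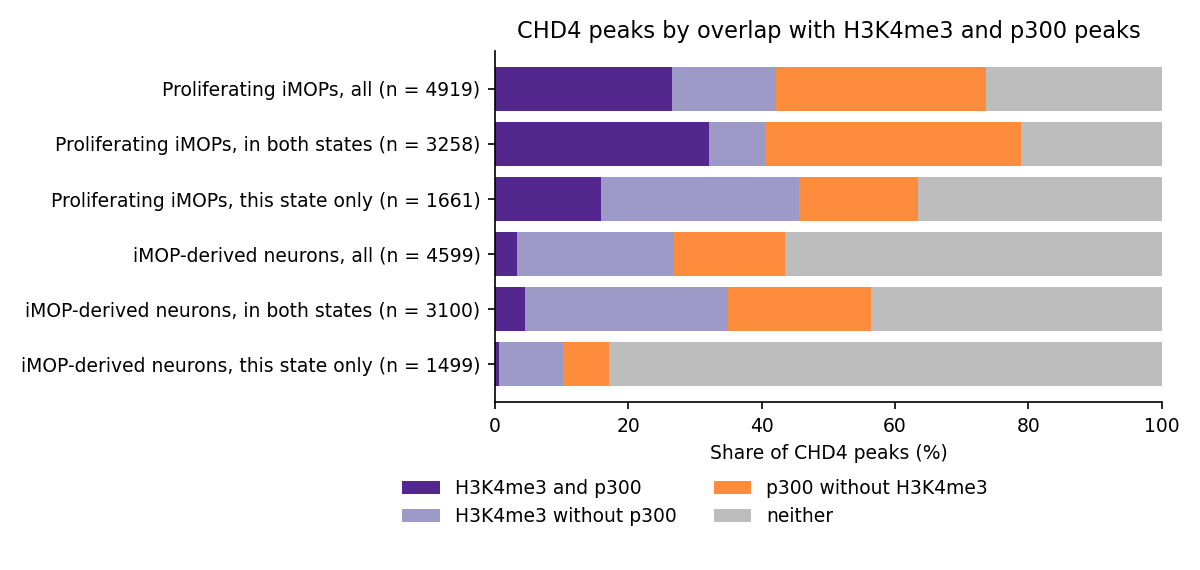
Bars show the share of CHD4 peaks (percent, horizontal axis) that overlap H3K4me3 and p300 peaks of the same state, for all peaks of each state and for peaks listed in both states or in that state only, with the number of peaks per bar. Peaks listed in neurons only stand apart, with 82.9% overlapping neither mark.

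In the opposite direction, nearly every p300 peak overlapped a CHD4 peak by at least 1 bp: 91.9% (90.8 to 92.8) of the proliferating p300 peaks and 962 of 965 (99.7%, 99.1 to 99.9) of the neuron ones. The 50-bp position of highest signal was shared between a p300 peak and a CHD4 peak for 40.6% (38.9 to 42.4) of proliferating and 54.2% (51 to 57.4) of neuron p300 peaks. H3K4me3 was different. Of the H3K4me3 peaks, 27.2% (26.2 to 28.3) overlapped CHD4 in proliferating cells and 22.0% (20.9 to 23.1) in neurons. Among genes with H3K4me3 within 1 kb of an annotated gene end, CHD4 was listed at the same or the other end of 1443 of 1627 genes that also had p300 at an end (88.7%, 87.1 to 90.2) and of 786 of 6597 that did not (11.9%, 11.1 to 12.7) in proliferating cells. In neurons it was listed at an end of 173 of 174 genes with p300 and of 1375 of 6387 without it (21.5%, 20.5 to 22.6). The high shares at genes with p300 largely restate the overlap of p300 peaks with CHD4 peaks and are not separate evidence.

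The sites listed in 1 state only differed in kind. Of the CHD4 peaks listed in proliferating cells only, 46.4% (44.0 to 48.9) lay within 1 kb of a gene end and 45.5% (43.1 to 47.9) overlapped H3K4me3. Of those listed in neurons only, 21.3% (19.3 to 23.5) lay at a gene end, 39.9% (37.4 to 42.4) elsewhere in a gene body and 38.8% (36.3 to 41.3) outside protein-coding genes, and 10.1% (8.66 to 11.8) overlapped H3K4me3. Only 7.54% (6.25 to 8.99) of the neuron-only peaks overlapped a neuron p300 peak. Proliferating CHD4 peaks with p300 were found again in neurons more often than those without p300, in 80.4% (78.9 to 81.8) against 46.7% (44.5 to 48.9) of cases. Those with p300 were also the stronger ones, with a median at the 68.3rd percentile of total signal, against the 22.4th for peaks with H3K4me3 alone and the 28.9th for peaks with neither, and the contrast was not matched for strength.

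CHD4 was listed at an annotated end of 2575 of 21887 protein-coding genes in proliferating cells and of 2177 in neurons: 1640 genes in both states, 935 in proliferating cells only and 537 in neurons only. The gene table used gives no strand, so an end can be a transcript start or a transcript end. Counting only ends that carried H3K4me3 in either state, the neuron-only genes numbered 267. Among CHD4 peaks at gene ends found in both states, the strongest by total signal in the proliferating list lay at Ddit4, a stress-induced inhibitor of mTOR signalling, Fcgr3, Acot7, the calcium channel subunit gene Cacng4, the histone gene H2bc11, Trmt61a, the Notch modifier gene Lfng and the collagen receptor gene Ddr1. Listed in proliferating cells only were the strongest peaks at Nfic, Gsk3b, Mknk2, H4c4, Snai1, a repressor of epithelial genes, Nrarp, a Notch feedback regulator, Zfp516 and Fasn, the fatty acid synthase gene. Among those listed in neurons only were H2bc18, the lipase gene Mgll and Hcn2, a pacemaker channel gene, whose CHD4 peak spanned 28700 bp on chromosome 10 (79702651 to 79731350, mm10).

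Axon guidance genes, to which the study's title points, carried CHD4 at gene ends in both states more often than most gene lists of the same size. Of 22 Eph receptors and ephrins, 9 carried CHD4 in each state against a mean of 2.57 and 2.18 in 10000 random lists. Of these, 8 were the same genes: Epha4, Epha7, Ephb3, Efna3, Efna4, Efna5, Efnb1 and Efnb2. Ephb4 was listed in proliferating cells only and Ephb2 in neurons only. Of 31 semaphorins, plexins and neuropilins, 12 carried CHD4 in proliferating cells and 13 in neurons (random means 3.62 and 3.09), with 9 in common, among them Sema6a, Sema6c, Nrp1, Nrp2 and Plxna2. Sema4a, Sema4c and Sema5b were listed in proliferating cells only, and Plxnb2, Plxnd1, Sema3f and Sema7a in neurons only. At Sema4c and Plxnd1 the strongest CHD4 peak lay at the other gene end from the strongest H3K4me3 peak of that state. Of 22 Slit, Robo and netrin genes, 4 and 5 carried CHD4 (random means 2.59 and 2.16), with Ntn1 in proliferating cells only, Srgap2 and Ntng2 in neurons only, and Slit1, Draxin and Ntn3 in both. The Eph and semaphorin counts exceeded all but 2.5% of the random lists in both states, also among genes with H3K4me3, and the Slit, Robo and netrin counts did not. With the stronger 50% of the peaks, the Eph count in proliferating cells was 3 (93.5th percentile) and no longer did, and the Slit, Robo and netrin count in neurons was 4 (98.8th percentile) and did. In that setting neither the Eph count in neurons (88.2nd percentile) nor the Slit, Robo and netrin count in neurons (90.4th) did so among genes with H3K4me3.

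Away from gene ends, within the gene body or 50 kb of an end, the Eph and ephrin genes had 17 CHD4 peaks at 8 genes in neurons, of which 13 were listed in neurons only, and 6 peaks at 3 genes in proliferating cells, of which none was listed in that state only. The semaphorin group had 30 such peaks in neurons (15 in neurons only) and 20 in proliferating cells (4 in that state only). The Slit, Robo and netrin group had 15 in neurons (7 in neurons only) and 16 in proliferating cells (6 in that state only). The strongest of them in both states lay inside Slit1, which encodes a repellent axon guidance ligand, on chromosome 19 (41682801 to 41698050 in proliferating cells and 41681301 to 41698050 in neurons). In the counts for each group, a peak near several member genes was counted for each of them. At Ephb2 (chromosome 4, 136647536 to 136836326) the neuron peak at the end without H3K4me3, from 136647601 to 136658200, covered a narrower proliferating peak further inside the gene, whereas at the end with H3K4me3 a CHD4 peak was listed in neurons only.

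**Figure D2:**
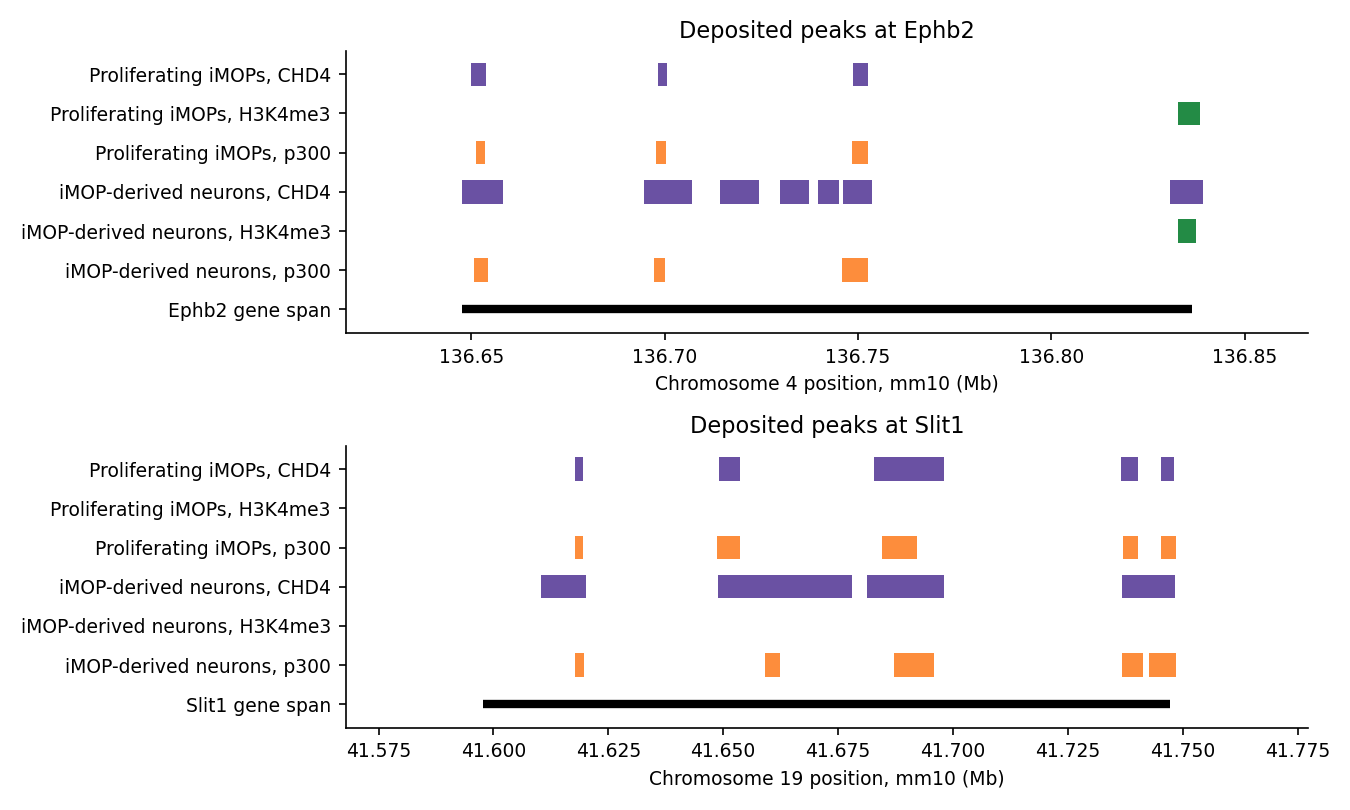
Horizontal bars show every deposited peak of the 6 libraries at Ephb2 (top) and Slit1 (bottom), by mm10 position in Mb, with the span of the gene as a black line. Neurons have 7 CHD4 peaks at Ephb2 against 3 in proliferating cells, and Slit1 has CHD4 and p300 but no H3K4me3 peak in either state.

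Genes of the NuRD complex and of the Notch pathway carried CHD4 in the highest shares. CHD4 was listed at 9 of 15 NuRD genes in each state (random means 1.75 and 1.48), including Chd4, Chd3, Hdac2, Mbd3 and Cdk2ap1 in both, Hdac1 in proliferating cells only and Mta1 in neurons only. The Mta1 peak lay just outside the gene, at the other end from its strongest neuron H3K4me3 peak. The Hdac1 peak, from 129512451 to 129516200 on chromosome 4, lay almost wholly outside the gene span, which begins at 129516104. Without strand, it cannot be told whether this end is the transcript start. The Notch list had 10 of 18 members in proliferating cells and 11 in neurons (2.12 and 1.79), all of the former shared between the states, among them the ligand gene Dll1 and the target gene Hes1, with the ligand gene Jag2 in neurons only. The CHD4 peaks at Hes1 differed in extent: 15100 bp across the whole gene in proliferating cells, and 3700 bp just outside 1 end of the gene in neurons. At Dll1 the CHD4, H3K4me3 and p300 peaks were each at or above the 97.8th percentile of their list by total signal in both states. Both lists exceeded all but 2.5% of random lists, also among genes with H3K4me3 and with the stronger 50% of the peaks, apart from the NuRD list in neurons, which then stood at the 76.8th percentile among H3K4me3 genes.

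Cell cycle genes carried CHD4 in both states, and differences between the states in their counts were not tested. Of 30 genes of cell cycle progression, 12 carried CHD4 in proliferating cells and 7 in neurons (random means 3.52 and 3.0). The cyclin genes Ccnd3, Ccna2 and Ccne2, the kinase gene Cdk6 and the replication genes Mcm6 and Pcna were listed in proliferating cells only, Mcm2 in neurons only, and Cdk2, Cdk4, Mcm7, E2f1, E2f2 and E2f3 in both. At Ccnd3 the strongest CHD4 peak lay at the other gene end from the strongest H3K4me3 peak of that state. H3K4me3 was kept at 24 of the 25 genes that had it, the exception being Ccnd1. Of 15 genes of cell cycle exit, 7 and 6 carried CHD4 (1.76 and 1.5), among them Cdkn1b, Btg1, Btg2 and Gadd45g in both states and Trp53 in proliferating cells only. Of 25 ribosomal protein genes, 9 and 5 did (2.93 and 2.5), a count close to that of other genes with H3K4me3 (6.77 and 5.65). The progression and exit counts exceeded all but 2.5% of random lists in both states and the ribosomal count in proliferating cells only. Among genes with H3K4me3 the exit counts did so in both states and the progression count in proliferating cells (98.6th percentile) but not in neurons (58.9th). The proliferating count lost this call with the 500-bp window (94.5th) and at ends with H3K4me3 (97.1st), and the neuron count lost the call against all genes with the 500-bp and 2.5-kb windows. With the stronger 50% of the peaks, only the exit count in proliferating cells (3, 97.7th percentile) still did against all genes, and none among genes with H3K4me3.

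Otic progenitor regulators had similar CHD4 counts in both states and fewer H3K4me3 calls in neurons. CHD4 was listed at 8 of 28 in proliferating cells and 7 in neurons (3.31 and 2.80): Sox2, Id1, Id2, Id3, Myc, Etv5 and Lfng in both, and Sox9 in proliferating cells only. Both counts exceeded all but 2.5% of random lists. Among genes with H3K4me3 only the neuron count did (97.8th percentile, against the 94.4th in proliferating cells), but not with the 2.5-kb window or the stronger 50% of the peaks, where it also failed against all genes (97.2nd). The proliferating count passed both comparisons with the stronger 50%. H3K4me3 was listed at 18 and 9 of them, with calls in proliferating cells only at genes that included Etv4, Etv5, Spry1, Id3, Fgfr2 and Fgfr3. Neuronal transcription factors showed the opposite count for CHD4, 3 of 25 in proliferating cells and 6 in neurons (2.95 and 2.44). The proneural gene Neurog2 and Insm1 and Scrt1 had CHD4 in both states, and Neurod2, Nhlh1 and Myt1 in neurons only, each without H3K4me3 at a gene end in either state. Neurod1 had no peak at a gene end in any list. The count of 6 passed all but 2.5% of random lists, but not among genes with H3K4me3 (95.1st percentile), with the 2.5-kb window (96.9th), with the stronger 50% of the peaks (3, 92.1st percentile) or at ends with H3K4me3 (3, 79.9th percentile).

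Genes of the neuronal cytoskeleton and axon had CHD4 at 5 of 28 in each state (Tubb3, Map1b, Stmn1 and Ncam1 in both, Map2 in proliferating cells only, Elavl3 in neurons only), synapse and ion channel genes at 4 and 5 of 30, neurotrophin and GDNF genes at 1 and 0 of 14, and remodellers outside NuRD with p300/CBP at 7 and 4 of 22, among them Smarca4 in proliferating cells only. Against all genes, of these lists only the remodellers in proliferating cells exceeded all but 2.5% of random lists, and not with the 500-bp window (93.9th percentile) or with the stronger 50% of the peaks, where 0 of its genes carried CHD4 (15.4th). Among genes with H3K4me3 only the cytoskeleton and axon list did, at the 97.8th percentile in proliferating cells and by a narrower margin in neurons, but in neither state with the stronger 50% of the peaks (86.8th and 77.3rd) and in neurons with neither other window. Markers of other cell types that a culture could hold had about as many members as random lists or fewer: 1 of 20 hair cell genes in each state (Myo6 in proliferating cells, Atoh1 in neurons), 1 of 16 glial genes (Erbb3, then Pmp22), 1 of 16 mesenchyme genes (Vim in both) and 1 of 14 blood and endothelium genes (Cd68 in both). Of 39 Hox genes 1 and 2 carried CHD4, and of 20 liver genes 2 in both states.

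**Figure D3:**
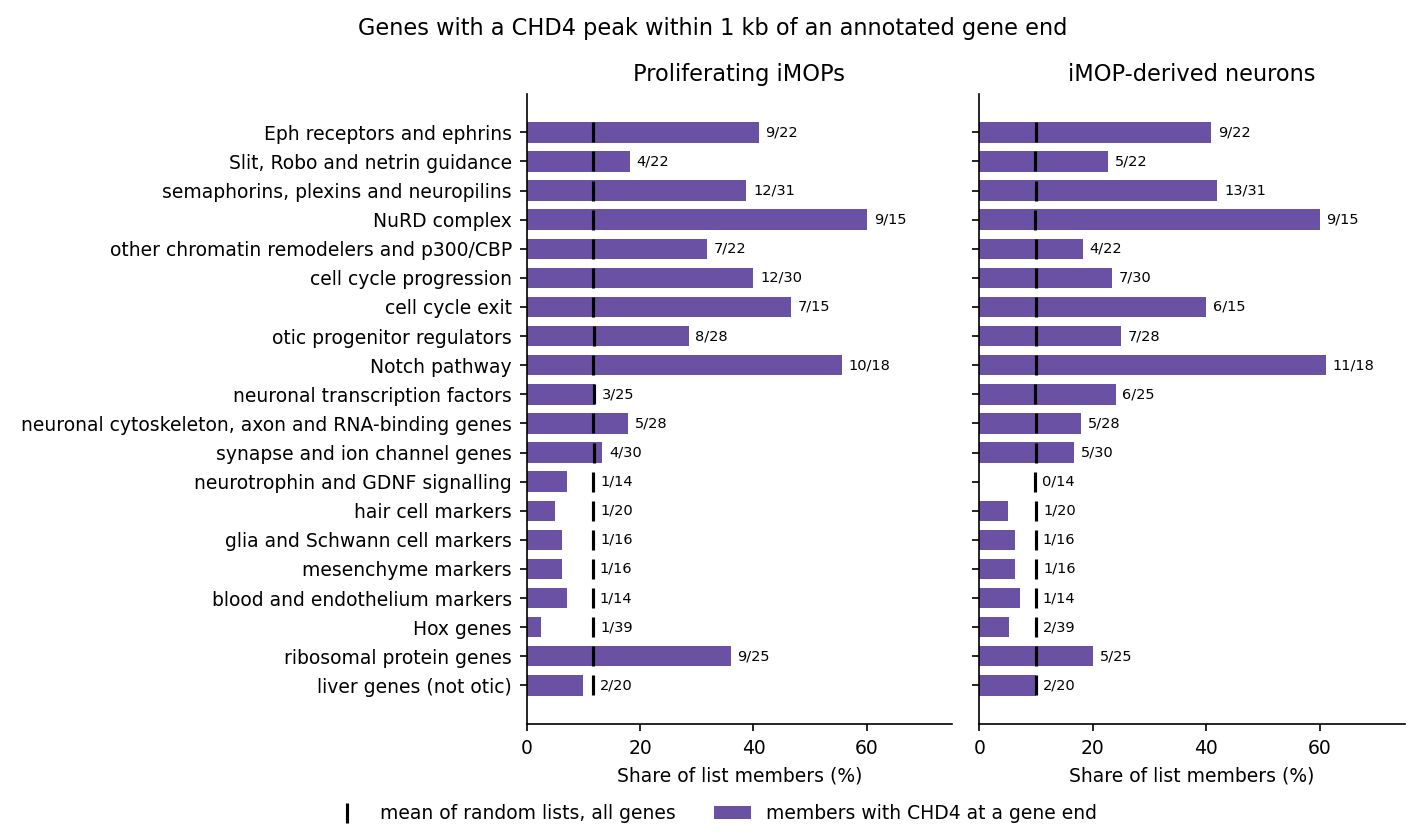
Bars show the share of each list's members (percent, horizontal axis) with a CHD4 peak within 1 kb of an annotated gene end in proliferating iMOPs (left) and iMOP-derived neurons (right), with the counts beside them, and vertical ticks the mean of 10000 random lists. NuRD (9 of 15 in each state) and Notch (10 and 11 of 18) stand highest.

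H3K4me3 peaks were shared between the states to a larger extent than p300 peaks. Of the neuron H3K4me3 peaks, 98.1% (97.7 to 98.4) overlapped a proliferating one, and 74.0% (73.0 to 75) of the proliferating peaks overlapped a neuron one. At gene ends, 6427 genes had H3K4me3 in both states, 1797 in proliferating cells only and 134 in neurons only. Among H3K4me3 peaks at an end of a protein-coding gene, the widest included those at the developmental regulators Pou3f3, Sox2 and Nfib in proliferating cells and at Nfib, Meis2 and Hoxa4 in neurons; at Sox2 the peak spanned 26300 bp in proliferating cells and 19950 bp in neurons. For p300, 23.5% (22.0 to 25.0) of the proliferating peaks overlapped a neuron peak and 75.6% (72.8 to 78.3) of the neuron peaks a proliferating one, and 196 genes had p300 at an end in both states, 1651 in proliferating cells only and 75 in neurons only. With p300 lists of equal size the overlaps were 48.2% and 48.3%. Of the p300 peaks, 44.8% (43.0 to 46.5) overlapped H3K4me3 in proliferating cells and 14.4% (12.2 to 16.8) in neurons.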

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

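Of the tests below, those on the composition of the p300 list, on peak width and on the length of the H3K4me3 list were chosen after the results were seen. The covered length of the lists was flagged because the antibodies went in opposite directions: neurons had 1.5 times the covered length of proliferating cells for CHD4, 0.853 times for H3K4me3 and 0.359 times for p300. Gene lists were flagged where more members carried CHD4 in neurons while fewer carried H3K4me3. The gain in CHD4 was 1 gene for Slit, Robo and netrin genes (H3K4me3 3 fewer), 1 for semaphorins and plexins (2 fewer), 1 for the Notch pathway (1 fewer), 3 for neuronal transcription factors (1 fewer) and 1 for Hox genes (1 fewer). None of these differences was tested, since each state has 1 library per antibody. Peaks on unplaced contigs, which no comparison of genes uses, numbered 31 for CHD4 and 24 for p300 in proliferating cells and 6 for CHD4 in neurons.

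Nearly all p300 peaks overlapped CHD4 peaks, which could mean shared sites or a signal common to both antibodies, such as open chromatin cut by the transposase. If the lists differed only in how deep they go, at least 80% of the strongest CHD4 peaks, as many as there are p300 peaks, were to overlap p300 in both states, and a share under 60% with its whole interval would have excluded it, bounds set for ranking by total signal. The shares were 76.8% in proliferating cells (75.3 to 78.3) and 68.5% in neurons (65.5 to 71.4), between those bounds, and 73.0% (71.4 to 74.5) and 59.8% (56.6 to 62.9) with CHD4 ranked by highest signal, where the neuron interval spans the lower bound. Against the p300 list being a sample of the strongest CHD4 peaks, 21.5% of neuron p300 peaks (18.9 to 24.2) lay at a gene end and 34.8% of those CHD4 peaks (31.8 to 37.9), or 28.4% (25.6 to 31.4) by highest signal, while in proliferating cells the p300 share was the higher one, 43.5% (41.8 to 45.3) against 38.5% (36.8 to 40.2) or 39.2% (37.5 to 40.9). A wider peak touches a gene end more easily, and width was not matched here. Over the whole lists, the median p300 and CHD4 peaks spanned 4050 and 5200 bp in neurons and 3350 and 3400 bp in proliferating cells. The widths of the strongest CHD4 peaks compared here were not measured, and ranking by total signal favours wide peaks. The neuron gap can therefore not be read as composition alone. A common background that adds to both lists without making up either one stays open, because the IgG libraries were not analysed here, and so does joint occupancy.

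Fewer p300 peaks overlapped H3K4me3 in neurons (14.4% against 44.8%). If the neuron list merely kept the strongest sites, strong proliferating p300 peaks with and without H3K4me3 were to be found again equally often. Among the 965 strongest, those at H3K4me3 were found in the neuron list in 33.4% of cases (28.8 to 38.2) and those away from it in 58.8% (54.6 to 62.9). These groups were not matched for strength within the 965, so the gap between them cannot decide on list length. In a comparison made after the results were seen, 41.9% (38.7 to 45.1) of the 965 strongest proliferating peaks lay at H3K4me3. In the equally long neuron p300 list the share was 14.4% (12.2 to 16.8), or 18.9% (16.4 to 21.5) against the proliferating H3K4me3 list. This argues against the length of the p300 list alone. The 965 proliferating peaks were picked by total signal, which favours wide peaks, and width was not matched. A loss of p300 from promoters during differentiation is one hypothesis, and a difference in signal over background between the 2 libraries, which no table here measures, may act in the same way.

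CHD4 peaks listed in neurons only lay away from H3K4me3. Weak peaks near the calling threshold do not account for all of the contrast with proliferating-only peaks. Among the stronger 50% of each list 7.81% of neuron-only peaks (5.56 to 10.6) and 26.1% of proliferating-only peaks (21.5 to 31.1) overlapped H3K4me3. This gap was smaller than the one over all such peaks (10.1% and 45.5%), so weak peaks may account for a part. Neuron-only peaks were also the wider ones, with a median of 4900 bp against 2950 bp, and against the longer proliferating H3K4me3 list 11.2% of them (9.65 to 12.9) overlapped, compared with 45.5% of proliferating-only peaks (43.1 to 47.9). A spread of CHD4 to sites outside promoters in neurons is a hypothesis that these overlaps leave standing, but the numbers of peaks away from gene ends were similar. Within gene bodies there were 1428 in proliferating cells and 1458 in neurons, and outside genes 1426 and 1465. Similar numbers do not show a similar extent, since the whole CHD4 list covered 19.4 Mb in proliferating cells and 29.2 Mb in neurons. A wide neuron peak can also overlap several narrower proliferating ones, as at Slit1. Over all CHD4 peaks, 42.0% and 36.4% lay at a gene end. A broader or noisier neuron CHD4 library may also list peaks away from H3K4me3, and the IgG libraries that could separate these explanations were not analysed here.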

How the results depend on the processing

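No paired analysis was possible because each group has 1 library. Depth is unknown, so no result could be matched on it; 2 of the alternatives, the restriction to numbered chromosomes, X and Y and the use only of gene ends with H3K4me3, were chosen after seeing the data. The neuron shares of CHD4 peaks at H3K4me3, at p300 and at gene ends stayed below the proliferating ones, and the share with neither mark above, in every setting run for them, but with lists of equal size the p300 difference shrank from 38.1 to 0.826 points and the neither-mark difference from 30.1 to 7.44 points. That setting leaves the neuron lists whole. It trims the proliferating lists from 4919 to 4599 peaks for CHD4, from 7472 to 5625 for H3K4me3 and from 3144 to 965 for p300. H3K4me3 does not enter the p300 share and the CHD4 list was cut little, so the p300 move comes mainly from the p300 trim. The neither-mark move draws on all of these lists and cannot be assigned to 1 of them. A share was called moved when it left its 95% interval, and a count, which has no interval, when it changed by more than 1.5 times. The restriction to chromosomes moved 0 of 19 results by this rule, a gap of up to 1 kb 0 of 12 and the 500-bp window 0 of 7. For the values that follow, beyond the trimming itself, the cause was not tested. With at least 50% of a peak covered, the overlap between states was 53.8% for neuron CHD4, 96.6% for neuron H3K4me3 and 71.4% for neuron p300; proliferating CHD4 overlapped p300 in 53.9% and neither mark in 29.3%, and neuron CHD4 overlapped H3K4me3 in 24.3%, p300 in 13.7% and neither in 64.1%. With the stronger 50% of each list, the overlap between states was 62.8% and 64.1% for CHD4 (proliferating, then neuron), 69.4% and 92.0% for H3K4me3 and 71.6% for neuron p300. Proliferating CHD4 then overlapped H3K4me3 in 30.1%, p300 in 55.6%, neither in 33.5% and a gene end in 36.6%, and neuron CHD4 overlapped H3K4me3 in 17.4%, neither in 64.7% and a gene end in 34.2%. In that setting 700 genes carried CHD4 in both states and 445 in proliferating cells only, and 5 gene lists stood above all but 2.5% of random lists in proliferating cells and 5 in neurons, against 9 and 8 with all peaks (9 and 6 with the 2.5-kb window). With lists of equal size the overlap was 68.9% and 65.7% for CHD4, 88.4% and 88.4% for H3K4me3 and 48.2% and 48.3% for p300, and proliferating CHD4 overlapped H3K4me3 in 38.2%, p300 in 20.8% and neither in 49.0%. The 2.5-kb window put 45.4% of proliferating and 39.1% of neuron CHD4 peaks at a gene end, and gene ends with H3K4me3 alone left 267 neuron-only genes.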

Other observations

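All tests in this part were chosen after the results were seen. Replication-dependent histone genes carried CHD4 in both states. Of 57 such genes in clusters on chromosomes 13 and 3, 43 carried CHD4 at a gene end in proliferating cells and 48 in neurons, on 20 CHD4 peaks in each state, since neighbouring genes share peaks. Shifting the gene set along the gene order gave means of 6.70 and 5.67, and the observed counts stood at percentile 100 in both states. The excess was not particular to CHD4. For p300 the counts were 41 and 19 (shifted means 4.81 and 0.705), above all but 2.5% of shifts in both states, and for H3K4me3 36 and 25 (21.4 and 17.1), above all but 2.5% in proliferating cells only. Histone genes have near-identical copies, so how reads that match several copies were placed could affect these counts, which was not tested.

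CHD4 peaks away from gene ends were counted for each list within the gene body or 50 kb of an end and set against random lists matched on gene length, 80 comparisons in all. A peak near several members of a list was counted for each of them, and the random lists did not keep neighbouring genes together. The Notch list had 16 peaks in proliferating cells (random mean 3.89) and 12 in neurons (3.45), and the otic regulators 17 in proliferating cells (5.75). Peaks listed in neurons only numbered 13 for Eph receptors and ephrins (2.84), 15 for semaphorins and plexins (4.18) and 10 for neuronal transcription factors (2.55), which also had 6 peaks listed in proliferating cells only (2.01). Of the 80 comparisons, 12 stood above all but 2.5% of random lists, where 2 would by chance; the comparisons share peaks and genes, so they are not independent.

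In proliferating cells 17 neighbouring CHD4 peaks, all listed in that state only, lay on chromosome 6 from 114496051 to 114630750 (mm10), where the table has no protein-coding gene end or body. The longest run in 1000 random relabellings was 15. The same interval held 15 proliferating p300 peaks and 0 peaks of the other lists. In neurons the longest run was 9, within the 14 reached by relabelling.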
